A study of Homo sapiens with 15 samples.

How the data were processed

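Total RNA from 15 samples of 2 established human cell lines, PC3 and P493-6, was made into single-indexed libraries with a stranded exon capture kit (TruSeq RNA Access) from 50 ng of RNA, per the labels' protocols. Cells grew in RPMI with 10% fetal bovine serum. Per the submitters' processing notes, the reads were aligned with STAR to hg38, counted per gene with HTSeq and compared with edgeR; versions, annotation and settings are not given in the sources used here. The values used compare PC3 with MYCi975, P493-6 with MYCi975 and P493-6 with tetracycline, each with its control, in a separate table.

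The authors deposited expression as CPM, the reads of a gene per 1000000 counted reads of the library, with no further scaling between libraries. This reading was checked on the values: every value of a library is a whole multiple of 1 step, so whole reads could be recovered for 100% of genes in all 3 tables within a tolerance of 0.001 reads. Every gene listed has a CPM above 1 in at least 2 of the 6 libraries of its table, so genes below that were removed before the tables were made. Per the file headers the tables also hold the authors' log2 fold change and mean log2 CPM, a likelihood ratio score, p-values with adjusted p-values, marks for genes that rose or fell, and a width in bases that was not used. The deposited marks follow an adjusted p below 0.01 for 100% of genes. The authors marked 3457 genes as higher and 3477 as lower in PC3, 1373 and 1236 in P493-6 with MYCi975, and 4985 and 5032 with tetracycline. Of these, 6927, 2506 and 9870 were called here in the same direction and none in the opposite, and the log2 fold changes of the authors and those computed here correlated across genes with r of 0.962, 0.96 and 0.954. Of 454 entries with no symbol, 144 were named from a reference table of gene identifiers. The control columns of both P493-6 tables are identical.

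Samples were grouped by line and treatment as the labels give them, 3 libraries per group. The choices of tests, gene lists and named genes were made before the data were examined. The plan for counts was edgeR's quasi-likelihood test with TMM scaling and, in P493-6, all 9 libraries. For normalized values the plan was limma within each table. Since the unit was CPM, limma 3.58.1 in R 4.3.3 was used, with trend and robust settings, on log2(CPM + 1). Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The direct contrast of MYCi975 and tetracycline used the 9 P493-6 libraries and the 12860 genes in both of their tables. The difference between the lines used the 12 libraries of control and MYCi975 and 11240 genes, with line, treatment and their interaction. In that contrast a positive value means the higher change in PC3. For each group of 3 against 3, "did not overlap" means that every library of one group lay above every library of the other.

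32 gene lists were fixed in advance, and those with at least 5 measured members were tested with camera (limma) at a preset correlation of 0.01 on log2(CPM + 1), with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Some calls were lost with an estimated correlation although that correlation lay below 0.01. A call lost in this way therefore does not by itself show that the members vary together. List members that rose or fell were counted with p-values adjusted over all genes and adjusted over the list alone. MYC is not a member of the MYC target list. Some list members belong to families with near-identical copies, whose reads HTSeq may have dropped or split, and these are called uncertain.

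Named genes follow a rule: for each comparison, MYC and MAX; the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 5 and groups that do not overlap; from each list up to 5 called members with the largest absolute change, or the 2 with the smallest p where none passed; and, for pairs of comparisons, the 6 genes per direction with the largest smaller-of-both absolute change. Genes named outside the rule are marked as named after their values were seen.

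The replicate spread was first described by the Pearson correlation of log2(CPM + 1) between libraries of a group, 0.9941 to 0.9967 over 15 pairs. Chi-square per gene between replicate libraries, which is 1 for counting error alone, was 2.11 to 6.07, so the libraries differed by more than counting. Depth was 8162582 to 15926008 reads per library. For a gene at 1 CPM that is about 8.163 to 15.93 reads, so fold changes of genes at a few CPM are imprecise.

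The gene and list tests were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known amounts, 50 per size. For PC3, limma recovered 30% of genes changed by 0.25 on the log2 scale, 70% at 0.5, 94% at 1 and 96% at 2, with 10 false calls among 13751 genes. For P493-6 with MYCi975 the shares were 42%, 76%, 84% and 98% with 6 false calls, for tetracycline 34%, 64%, 82% and 94% with 8, for the direct contrast 34%, 66%, 96% and 98% with 12, and for the difference between lines 32%, 60%, 88% and 98% with 6. No simulated gene was called in the wrong direction, and unmoved lists had camera p from 0.181 to 0.803. Each simulated gene was drawn on its own, so these lists do not test camera where members vary together.

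Alternatives planned in advance were RLE scaling, DESeq2 1.42.0 and limma voom on the recovered reads, a mean CPM of at least 5, a pseudocount of 0.1, the replicate number as a block, each replicate left out in turn, the tetracycline libraries added to the fit of the difference between the lines, and an absolute log2 fold change of at least 1. A test of the MYC target list without CDK4, MCM4, MCM5, PLK1, PLK4 and UNG was planned too. Added as alternatives after seeing the data were TMM scaling, edgeR 4.0.16 quasi-likelihood on the recovered reads, all 9 P493-6 libraries in 1 fit, lists with a pseudocount of 0.1, and overlaps recomputed with edgeR, with replicates left out and with the block. Of these, TMM scaling, edgeR and the fit of all 9 libraries had been the plan for counts. Transcript lengths and GC content were those of the longest transcript of each gene in the GENCODE annotation of the same genome build. The R package data.table, version 1.17.8, handled the values, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Some single genes of the lists are not reported here.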

Results

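Messenger RNA was sequenced from 2 human cell lines to ask whether MYCi975, a small molecule made to inhibit the transcription factor MYC, changes the expression of genes that MYC controls. PC3 is a prostate cancer line with abundant MYC of its own. P493-6 is a B cell line, described in the labels as a Burkitt lymphoma line that overexpresses MYC, in which tetracycline turns an introduced MYC gene off. PC3 cells received DMSO or 8 µM MYCi975, and P493-6 cells received DMSO, 6 µM MYCi975 or 0.1 µg/ml tetracycline, for 24 h. Each of the 5 groups had 3 libraries, 15 in all, prepared by capture of exon sequences with strand kept. Depth ran from 13174502 to 15926008 reads per library in PC3 controls and from 13571476 to 14146453 reads in PC3 with MYCi975. In P493-6 it ran from 9774101 to 12212555 reads in controls, 10016138 to 11691303 reads with MYCi975 and 8162582 to 9895173 reads with tetracycline. Expression was in CPM, the reads of a gene per 1000000 reads of its library. Rises and falls below are therefore relative to the other genes of a library, and changes in total RNA per cell were not tested. Group values below are the mean CPM ± SD over 3 libraries, log2 fold changes were taken on log2(CPM + 1), with single values in parentheses after a gene being log2 fold changes, and adjusted p-values are from limma for genes and from camera for gene lists. The added 1 CPM pulls the fold changes of genes with few reads toward 0. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

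MYC itself (ENSG00000136997, chromosome 8, 127735434 to 127741434 on the plus strand of hg38) was measured in every library. In P493-6 controls it stood at 4692, 4701 and 4791 CPM, with MYCi975 at 5138, 5084 and 5132 CPM, and with tetracycline at 152.3, 144.9 and 149.8 CPM. Tetracycline lowered MYC from 4728 ± 54.8 to 149.0 ± 3.75 CPM (log2 fold change −4.98, SE 0.036, adjusted p = 2.76e-49). MYCi975 did not lower MYC mRNA in either line. In P493-6 it rose to 5118 ± 29.4 CPM (log2 fold change 0.11, SE 0.032, adjusted p = 0.00535). In PC3, MYC was 301.1, 300.4 and 309.3 CPM in controls and 378.1, 359.4 and 385.9 CPM with MYCi975, a rise of 0.30 on the log2 scale (SE 0.032, adjusted p = 3.99e-14). The tables hold 1 entry for MYC and do not separate the introduced gene of P493-6 from the cell's own copy. MAX, the partner with which MYC binds DNA, had log2 fold changes of −0.09 in PC3 (adjusted p = 0.0592), 0.02 in P493-6 with MYCi975 (adjusted p = 0.81) and 0.00 with tetracycline (adjusted p = 0.997). The value for MAX in PC3 passed the threshold without PC3 MYCi975 replicate 2 (−0.11, adjusted p = 0.0457).

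**Figure D1:**
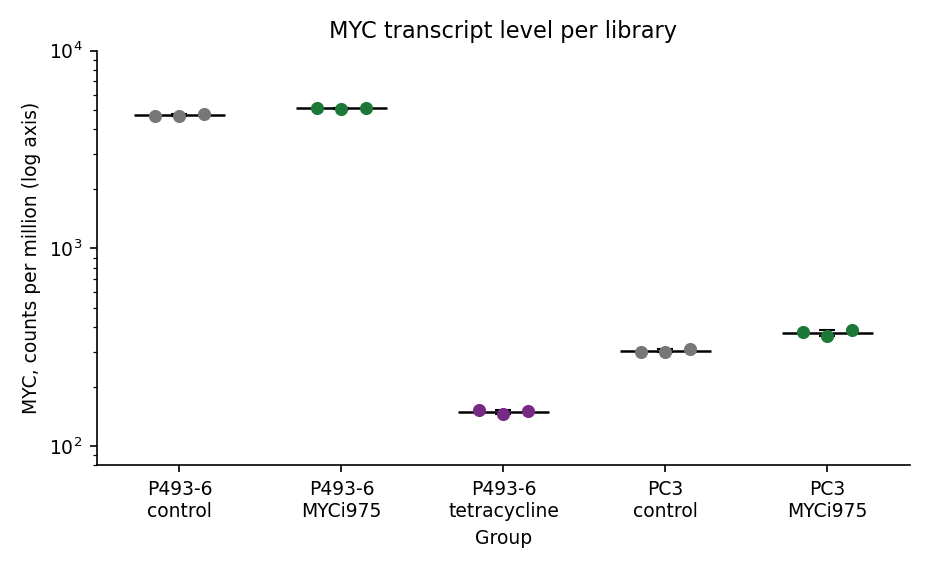
MYC expression in CPM (log axis) in each of the 15 libraries by group; points are libraries, lines are group means and bars are the SD over 3 libraries. The 3 tetracycline libraries sit between 144.9 and 152.3 CPM, below every control and MYCi975 library of P493-6 (4692 to 5138 CPM), and the PC3 libraries with MYCi975 sit between 359.4 and 385.9 CPM, above the PC3 controls.

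The comparison of PC3 with and without MYCi975 asked whether the compound alters MYC target genes in a line that makes its own MYC. PC3 cells given MYCi975 expressed more of the genes of the integrated stress response, the program that cells switch on when amino acids are short or proteins misfold, and fewer transcripts for DNA replication, mitosis and MYC targets. The largest rise was in TRIB3, a pseudokinase induced by stress (ENSG00000101255, chromosome 20, 362835 to 397559 on the plus strand), from 45.1 ± 1.87 to 610.4 ± 19.2 CPM (log2 fold change 3.73, SE 0.038, adjusted p = 4.96e-90). The largest fall was in PHACTR3, a regulator of actin and protein phosphatase 1, from 94.5 ± 0.592 to 15.1 ± 1.85 CPM (−2.57, SE 0.064, adjusted p = 7.98e-54). Of 13751 genes tested, 8137 changed, 3993 upward and 4144 downward, and the median absolute log2 fold change among them was 0.388. A change of at least 2-fold was reached by 315 of the genes that rose and by 192 of those that fell. The groups did not overlap for 61.9% of genes, against 10% by chance.

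Of 28 measured integrated stress response genes in PC3, 27 rose and 1 fell, with a median log2 fold change of 1.57 (adjusted p = 4.98e-29). DDIT4, an inhibitor of the growth kinase mTOR, rose from 3.68 ± 0.348 to 44.7 ± 2.31 CPM (3.29), SESN2, a leucine sensor, by 2.99, CHAC1, an enzyme that degrades glutathione, by 3.03 and DDIT3, which encodes the stress transcription factor CHOP, by 2.93. ASNS, which makes asparagine, rose from 23.3 to 159.6 CPM (2.73, adjusted p = 1.09e-66), and NUPR1, a stress-induced chromatin protein, rose by 3.25 (adjusted p = 4.99e-30). The 1 member that fell was ATF5 (−0.66, adjusted p = 1.43e-17), named here after its value was seen. The unfolded protein response of the endoplasmic reticulum moved with it: 18 of 22 genes rose and none fell (median 0.37, adjusted p = 5.9e-10), among them the chaperone HSPA5 (536.4 ± 2.5 to 1475 ± 72.2 CPM), HERPUD1 (1.83) and the stress sensor ERN1 (2.33). Targets of NRF2, which answers oxidative stress, rose in 21 of 25 genes and fell in 2 (median 0.53, adjusted p = 3.36e-09), with the cystine transporter SLC7A11 at 1.94 and the haem-degrading enzyme HMOX1 at 1.83. Lysosome and autophagy genes rose in 26 of 31 and fell in 2 (median 0.43, adjusted p = 1.16e-10), and the autophagy receptor SQSTM1 went from 811.6 ± 18.7 to 2263 ± 38.2 CPM.

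All 30 mitosis genes fell in PC3 with MYCi975 (median −0.92, adjusted p = 4.32e-25), including the kinesin KIF20A from 110.2 ± 1.28 to 34.3 ± 0.139 CPM (−1.65), TOP2A (−1.19) and the proliferation marker MKI67 (−1.39, adjusted p = 0.000296). Of 36 genes of DNA replication and the G1/S transition, 35 fell and none rose (median −0.90, adjusted p = 2.31e-21), among them CCNE2, a cyclin of S phase entry (−1.74), UHRF1, which maintains DNA methylation (−1.47), and the phosphatase CDC25A (−1.38). Of the 57 MYC targets, 48 fell, 3 rose and 6 did not pass (median −0.41, adjusted p = 5.22e-13). The helicase subunits MCM4 (210.2 ± 3.69 to 77.8 ± 2.27 CPM, −1.42) and MCM5 (−0.87), the mitotic kinases PLK1 (−1.40) and PLK4 (−0.78) and the uracil-removing enzyme UNG (−1.33) had the largest falls of that list. With these genes and CDK4 left out, the list kept its direction and its call in all 3 comparisons with control. HK2, a hexokinase, and SUPV3L1, a mitochondrial helicase, were among the 3 that rose (0.34 and 0.29) and are named here after their values were seen. Nucleotide and one-carbon synthesis genes fell in 20 of 27 and rose in 4 (median −0.37, adjusted p = 5.69e-06), with RRM2, a subunit of ribonucleotide reductase, at −1.45 and thymidylate synthase TYMS at −1.27. MTHFD2, a mitochondrial folate enzyme in the same list, went the other way (1.09).

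Ribosome biogenesis and RNA polymerase I genes fell in 28 of 36 and rose in 2 in PC3 with MYCi975 (median −0.28, adjusted p = 1.05e-07; adjusted p = 0.0904 with an estimated correlation), among them NOP58 (−0.75), RRS1 (−0.74) and nucleolin NCL (−0.61). Genes for mitochondrial ribosomal proteins fell in 46 of 75 and rose in 4 (median −0.20, adjusted p = 5e-05; adjusted p = 0.142 with an estimated correlation). Genes for cytosolic ribosomal proteins rose in 63 of 78 and fell in 3 (median 0.15, adjusted p = 9.91e-09; adjusted p = 0.299 with an estimated correlation), and because these genes have many near-identical pseudogenes the values of single members such as RPL12 (0.39) and RPL37A (0.39) are uncertain. Heat shock response genes fell in 14 of 16 and rose in none (median −0.66, adjusted p = 3.77e-10), with the chaperone HSP90AA1 dropping from 7378 ± 242 to 3740 ± 127 CPM and its co-chaperone DNAJA1 at −0.88. Glycolysis genes fell in 14 of 21 and rose in 4 (median −0.29, adjusted p = 0.00114; adjusted p = 0.14 with an estimated correlation), LDHA from 1488 ± 34.3 to 740.3 ± 12.3 CPM with PKM at −0.60, while HK1 rose by 0.78.

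NF-kB and inflammatory genes rose in 11 of 16 and fell in 2 in PC3 with MYCi975 (median 0.58, adjusted p = 0.000444), among them the chemokines IL8 (2.06) and CXCL2 (2.04). Genes of the epithelial-mesenchymal transition rose in 15 of 28 and fell in 3 (median 0.25, adjusted p = 0.000539), with integrin ITGB3 rising by 1.65 and the growth factor CTGF going the other way (−1.16). Antigen presentation by MHC class I rose in 12 of 17 genes and fell in none (median 0.32, adjusted p = 0.0011; adjusted p = 0.0904 with an estimated correlation). Interferon-stimulated genes rose in 20 of 34 and fell in 5 (median 0.23, adjusted p = 0.0116; adjusted p = 0.124 with an estimated correlation), with RSAD2 (1.94) and DDX60 (11.3 to 33.6 CPM) highest. Hypoxia response genes rose in 7 of 16 and fell in 1 (median 0.13, and 0.195 without PC3 control replicate 2; adjusted p = 0.0181; adjusted p = 0.142 with an estimated correlation), including NDRG1 (1.15) and the vessel growth factor VEGFA (1.01). p53 targets rose in 11 of 24 and fell in 6 (median 0.08, adjusted p = 0.0465; adjusted p = 0.136 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 1.71 and the cytokine GDF15 at 3.40. PC3 is known as a line without working p53, and the call on this list was also lost with a pseudocount of 0.1 (adjusted p = 0.0508) and without PC3 MYCi975 replicate 1 (adjusted p = 0.058).

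Among single genes outside the lists, HKDC1, a hexokinase relative, rose by 2.78 in PC3. MAP2K6, a kinase that activates p38, fell from 14.7 ± 1.4 to 1.79 ± 0.396 CPM (−2.50), and FAM111B (−2.23), the protocadherin PCDH18 (−2.05) and the receptor GPR110 (−1.93) also fell. The histone genes H2BC3 (−2.02), H2BC14 (−1.97) and H2AC4 (−1.95) were also among the 8 largest falls, and their values are uncertain because histone genes come in near-identical copies. Camera called 19 of 26 lists in PC3, and 11 of these held with an estimated correlation. Counts of genes adjusted over the list alone were the same as over all genes, except for cytosolic ribosomal proteins (65 rose, 4 fell), mitochondrial ribosomal proteins (4 rose, 47 fell), glycolysis (5 rose, 14 fell), interferon-stimulated genes (21 rose, 5 fell) and the epithelial-mesenchymal transition (15 rose, 4 fell).

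The comparison of P493-6 with and without MYCi975 asked the same of a line whose MYC comes mainly from an introduced gene. P493-6 cells given MYCi975 also expressed more integrated stress response genes and fewer transcripts of MYC target, DNA replication and mitosis genes, and they expressed more hypoxia response and MHC class II genes, although the calls on mitosis and hypoxia were lost with an estimated correlation (adjusted p = 0.057 for both). INHBE, a subunit of the hormone activin E, had the largest rise, from 1.84 ± 0.269 to 12.8 ± 1.8 CPM (log2 fold change 2.27, SE 0.152, adjusted p = 5.92e-16). ASS1, an enzyme of arginine synthesis (ENSG00000130707, chromosome 9, 130444929 to 130501274 on the plus strand), went from 51.8 ± 4.16 to 175.8 ± 4.73 CPM (1.75, SE 0.054, adjusted p = 4.42e-29). PPP1R3A, a glycogen-targeting subunit of protein phosphatase 1, had the largest fall (15.4 ± 0.482 to 5.32 ± 1.03 CPM, −1.39, SE 0.128, adjusted p = 9.37e-12). Of 12998 genes tested, 3713 changed, 1375 upward and 2338 downward, with a median absolute log2 fold change of 0.272, and 22 rose and 6 fell by at least 2-fold. The split by direction depended on scaling, since with TMM factors 1819 genes rose and 1690 fell. The groups did not overlap for 40% of genes, against 10% by chance.

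Of 27 measured integrated stress response genes in P493-6, 24 rose with MYCi975 and none fell (median 0.34, adjusted p = 3.59e-26). The lipoprotein receptor VLDLR (2.05), CHAC1 (1.77), the secreted hormone STC2 (1.44), the transcription factor ATF3 (1.29) and DDIT4 (25.3 ± 4.59 to 61.1 ± 3.11 CPM, 1.25) had the largest rises. SLC6A9, a glycine transporter outside the lists, rose by 1.62 and the kinase gene ALPK2 by 1.25. Unfolded protein response genes rose in 9 of 23 and fell in 4 (median 0.04, adjusted p = 0.00068; adjusted p = 0.057 with an estimated correlation), including ERN1 (1.08) and HERPUD1 (0.73). Hypoxia response genes rose in 11 of 13 and fell in none (median 0.56, adjusted p = 6.65e-13; adjusted p = 0.057 with an estimated correlation), with BNIP3L, a mitophagy receptor, at 0.85, the peptide hormone ADM at 0.95 and the oxygen sensor EGLN1 at 0.68. Glycolysis genes rose in 12 of 20 and fell in none (median 0.11, adjusted p = 2.26e-07; adjusted p = 0.064 with an estimated correlation), and PFKFB4 (1.02) and PDK1 (0.87), regulators of glucose use, rose most.

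Of the 57 MYC targets, 35 fell, 1 rose and 21 did not pass in P493-6 with MYCi975 (median −0.19, adjusted p = 6.72e-12). The chaperonin subunit HSPE1 (−0.49), MCM4 (573.8 ± 22.6 to 424.4 ± 10.5 CPM, −0.43), and the ribosome assembly genes TCOF1 (−0.42), UTP20 (−0.40) and NOP56 (−0.38) fell most, and the 1 member that rose was HK2 (0.19, adjusted p = 0.0016), named here after its value was seen. DNA replication and G1/S genes fell in 34 of 36 and rose in none (median −0.31, adjusted p = 4.31e-20), with CCNE2 at −0.67 and the replication checkpoint protein CLSPN at −0.64. Mitosis genes fell in 27 of 30 and rose in none (median −0.26, adjusted p = 4.19e-15; adjusted p = 0.057 with an estimated correlation). Nucleotide and one-carbon synthesis genes fell in 16 of 27 and rose in 2 (median −0.16, adjusted p = 0.00119; adjusted p = 0.114 with an estimated correlation), including RRM2 (−0.74). Heat shock response genes fell in 12 of 15 and rose in 1 (median −0.31, adjusted p = 1.59e-09), with HSP90AA1 going from 3386 ± 136 to 2386 ± 75.6 CPM. Cholesterol synthesis genes fell in 14 of 24 and rose in 1 (median −0.23, adjusted p = 7.43e-05; adjusted p = 0.057 with an estimated correlation), with HMGCS1 at −0.54 and MVK at −0.49. Fatty acid synthesis genes fell in 6 of 14 and rose in none (median −0.15, adjusted p = 0.00244; adjusted p = 0.057 with an estimated correlation), with the lipid regulator SREBF1 at −0.51.

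MHC class II presentation genes, which show peptides to T cells, rose in 12 of 13 and fell in none with MYCi975 (median 0.42, adjusted p = 7.44e-14), HLA-DPB1 from 144.7 ± 2.83 to 227.9 ± 2.25 CPM (0.65) and HLA-DQA1 by 0.61. MHC class I presentation genes rose in 9 of 18 and fell in 1 (median 0.17, adjusted p = 3.28e-08; adjusted p = 0.057 with an estimated correlation), with HLA-E at 0.55, and reads of HLA genes can be shared between family members. NF-kB and inflammatory genes rose in 10 of 17 and fell in none (median 0.30, adjusted p = 2.74e-07; adjusted p = 0.057 with an estimated correlation), among them TNFAIP3, which restrains NF-kB (0.62). Lysosome and autophagy genes rose in 9 of 31 and fell in 2 (median 0.12, adjusted p = 0.00138; adjusted p = 0.057 with an estimated correlation), with the lysosomal proteins GRN and TPP1 both at 0.42 and the enzyme GLA at −0.43. Interferon-stimulated genes went both ways: 7 of 33 rose and 5 fell (adjusted p = 0.553), with a median of −0.07 and a mean of −0.04 although the test pointed up. CXCL10 rose by 0.72, while MX1 and IFI44L both fell by 0.83 on the log2 scale.

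Cytosolic ribosomal protein genes rose in 70 of 78 and fell in none in P493-6 with MYCi975 (median 0.23, adjusted p = 1.84e-37; adjusted p = 0.057 with an estimated correlation), with the uncertain members RPL12 (0.41) and RPS2 (0.37) among them. Ribosome biogenesis and RNA polymerase I genes fell in 23 of 36 and rose in none (median −0.16, adjusted p = 1.9e-06; adjusted p = 0.147 with an estimated correlation), including NCL (−0.34). Mitochondrial ribosomal protein genes fell in 39 of 75 and rose in none (median −0.18, adjusted p = 1.98e-09; adjusted p = 0.057 with an estimated correlation), including MRPL18 (−0.38). Genes encoded by the mitochondrial genome rose in 9 of 13 and fell in none (median 0.39, adjusted p = 4.99e-15; adjusted p = 0.0945 with an estimated correlation), MT-CO1 from 4137 ± 136 to 5759 ± 617 CPM and MT-ND4L by 0.50. BCYRN1 (−1.06) and RNVU1-27 (−0.89), small noncoding RNAs with related copies elsewhere in the genome, fell but are uncertain, and GUCY1B3, a subunit of guanylate cyclase, fell by 0.84 on the log2 scale.

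Camera called 19 of 28 lists in P493-6 with MYCi975, and 5 of these held with an estimated correlation: the integrated stress response, MYC targets, DNA replication and G1/S, heat shock and MHC class II. Adjusted over the list alone, the counts grew to 38 MYC targets that fell, 25 integrated stress response genes that rose, 29 mitosis genes that fell, 13 heat shock genes that fell, 75 cytosolic ribosomal protein genes that rose and 47 mitochondrial ribosomal protein genes that fell. In the same way, 11 mitochondrially encoded and 13 glycolysis genes rose, 16 cholesterol genes fell, 24 ribosome biogenesis genes fell and 1 rose, 4 nucleotide synthesis genes rose, and 10 unfolded protein response genes rose. Likewise 5 BCL2 family and 5 NRF2 genes fell, 8 B cell identity genes rose, and 4 MYC network factors rose and 2 fell. The counts of the other tested lists were the same. Markers of T cells and myeloid cells (5 measured) showed 1 fall and no rise (median −0.10, adjusted p = 0.977). Leaving out each replicate gave medians from −0.102 to 0.01.

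The comparison of P493-6 with and without tetracycline asked what changes when the introduced MYC gene is turned off. With tetracycline, interferon-stimulated, inflammatory, antigen presentation and B cell identity genes were higher, and genes for ribosome assembly, mitochondrial ribosomes, nucleotide and lipid synthesis, DNA replication and MYC targets were lower, although the calls on both lipid lists were lost with an estimated correlation (adjusted p = 0.0702). IFI6, an interferon-induced mitochondrial protein (ENSG00000126709, chromosome 1, 27666061 to 27672218 on the minus strand), rose from 1.12 ± 0.0937 to 175.5 ± 15.5 CPM (log2 fold change 6.38, SE 0.102, adjusted p = 1.82e-37). After MYC, DDN fell most, from 66.3 ± 1.52 to 1.61 ± 0.104 CPM (−4.69, SE 0.116, adjusted p = 2.46e-31). Of 13703 genes tested, 10702 changed, 4957 upward and 5745 downward, with a median absolute log2 fold change of 0.803 (0.272 with MYCi975), and 1849 rose and 2219 fell by at least 2-fold. The split by direction depended on scaling, since with TMM factors 5382 genes rose and 5367 fell. The groups did not overlap for 78.4% of genes, against 10% by chance. All of these changes are relative to the other genes, so they do not give amounts per cell. The controls received DMSO and tetracycline was given in water, so turning MYC off, tetracycline itself and the change of vehicle act together in this comparison.

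All 57 MYC targets changed with tetracycline, 55 downward and 2 upward (median −2.11, adjusted p = 5.89e-21). Spermidine synthase SRM fell from 387.8 ± 14.1 to 38.8 ± 5.1 CPM (−3.29), the chaperonin HSPD1 from 1447 ± 34.9 to 152.0 ± 5.04 CPM (−3.24), and the nucleolar genes RRP9 (−3.44), MYBBP1A (−3.34) and NOP16 (−3.14) likewise fell. MAP3K6, a stress kinase, was 1 of the 2 that rose (1.27, adjusted p = 8.03e-08), named here after its value was seen. All 36 ribosome biogenesis and RNA polymerase I genes fell (median −2.14, adjusted p = 5.01e-18), among them BOP1 (−2.94) and EBNA1BP2 (−2.91). Mitochondrial ribosomal protein genes fell in 73 of 75 and rose in none (median −1.07, adjusted p = 3.03e-15), including MRPL4 (−2.51) and MRPL12 (−2.22). Cytosolic ribosomal protein genes rose in 60 of 78 and fell in 8 (median 0.22, adjusted p = 7.39e-06; adjusted p = 0.448 with an estimated correlation), with the uncertain member RPS27 at 0.91.

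Nucleotide and one-carbon synthesis genes fell in 26 of 27 and rose in 1 with tetracycline (median −1.57, adjusted p = 1.31e-12), with the nucleoside kinase NME1 (−3.43), the folate enzyme MTHFD1L (−3.35) and the purine enzyme PAICS (−2.99). Fatty acid synthesis genes fell in 11 of 14 and rose in 2 (median −1.28, adjusted p = 0.000234; adjusted p = 0.0702 with an estimated correlation), with the desaturase SCD going from 857.0 ± 34.3 to 74.2 ± 2.69 CPM and fatty acid synthase FASN from 873.0 ± 23.5 to 80.5 ± 2.45 CPM. Cholesterol synthesis genes fell in 19 of 24 and rose in 2 (median −0.79, adjusted p = 0.000268; adjusted p = 0.0702 with an estimated correlation), including DHCR7 (−2.90). Glycolysis genes fell in 16 of 20 and rose in 3 (median −1.15, adjusted p = 2.34e-05; adjusted p = 0.113 with an estimated correlation), LDHA from 1563 ± 12.5 to 292.9 ± 6.9 CPM. Heat shock response genes fell in 14 of 15 and rose in none (median −1.78, adjusted p = 1.35e-06), with FKBP4 at −3.89 and HSP90AB1 at −2.20. Integrated stress response genes fell in 18 of 26 and rose in 7 (median −1.15, adjusted p = 0.00208). The serine synthesis enzymes PSAT1 (−3.09) and PHGDH (−2.30), the amino acid transporter SLC7A5 (−2.87) and ASNS (−1.62) fell, while ATF3 (1.45) and DDIT4 (0.98) rose. Unfolded protein response genes fell in 13 of 23 and rose in 4 (median −0.22, adjusted p = 0.0532), which passed the threshold without P493-6 control replicate 1 (adjusted p = 0.0466), P493-6 control replicate 2 (adjusted p = 0.0486) or P493-6 tetracycline replicate 1 (adjusted p = 0.0499).

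DNA replication and G1/S genes fell in 35 of 36 and rose in 1 (median −1.19, adjusted p = 9.3e-10) with tetracycline, including the polymerase subunit POLE2 (−2.33) and CDC25A (−2.12). Mitosis genes fell in 20 of 30 and rose in 3 (median −0.32, adjusted p = 0.0198; adjusted p = 0.322 with an estimated correlation), with the checkpoint gene MAD2L1 at −1.69 and the phosphatase CDC25C at 0.73. The call on mitosis genes was lost with TMM (adjusted p = 0.0506) and RLE scaling (adjusted p = 0.0509). Among single genes outside the lists, CAMKV (−4.62), HPDL (−4.57), FJX1 (−4.23), the neuropeptide NPW (−4.21), MTSS1L (−4.18) and the RNA polymerase I subunit gene CD3EAP (−4.11) fell most. Genes encoded by the mitochondrial genome rose in 10 of 13 and fell in none (median 0.31, adjusted p = 0.00432; adjusted p = 0.411 with an estimated correlation), MT-CO1 from 4137 ± 136 to 6885 ± 571 CPM.

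Of 41 measured interferon-stimulated genes, 40 rose and 1 fell with tetracycline (median 3.99, adjusted p = 2.75e-23). Only 33 of the 41 were also measured with MYCi975 against the same controls. The others needed the tetracycline libraries to pass the CPM filter, which tilts the count of rises upward. The antiviral GTPase MX1 rose from 23.4 ± 2.21 to 977.2 ± 68.4 CPM (5.33), OAS3, a sensor of double-stranded RNA, by 5.42, IFI44L by 5.38, DDX60 by 5.31 and EPSTI1 by 4.92. The 1 member that fell was MX2 (160.9 to 126.5 CPM, −0.35, adjusted p = 3.74e-08), named here after its value was seen. SLFN5 and HELZ2, interferon-inducible genes outside the list, rose by 5.70 and 5.04. All 19 NF-kB and inflammatory genes rose (median 2.001, adjusted p = 4.34e-11), of which 17 were also measured with MYCi975. Among them TNF went from 1.19 ± 0.43 to 33.4 ± 2.44 CPM (3.99) and LTB rose by 3.53. All 24 B cell identity genes rose (median 1.55, adjusted p = 3.36e-13), CD72 from 11.8 ± 0.0817 to 148.4 ± 5.32 CPM, CD37 by 2.32 and the B cell receptor subunit CD79B by 2.06. All 13 MHC class II presentation genes rose (median 1.99, adjusted p = 1.24e-10), including HLA-DOB (2.51) and HLA-DQA1 (2.34). MHC class I presentation genes rose in 15 of 18 and fell in 3 (median 1.04, adjusted p = 8e-06), with HLA-E going from 50.9 ± 2.52 to 460.7 ± 11.2 CPM.

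Markers of T cells and myeloid cells rose in the same tetracycline libraries: of 16 fixed markers 8 were measured, and all 8 rose (median 1.58, adjusted p = 0.000794). Only 5 were also measured with MYCi975 against the same controls. Measured genes had a CPM above 1 in at least 2 of the 6 libraries compared. Markers measured only here needed the tetracycline libraries to pass, which tilts the count of rises upward. LYZ went from 4.96 ± 0.435 to 58.6 ± 3.76 CPM, ITGAM from 4.72 ± 1.05 to 77.8 ± 1.65 CPM and CD3G from 3.23 ± 0.972 to 17.4 ± 0.263 CPM. Summed over the 8 markers, expression rose from 25.8 ± 2.92 to 190.2 ± 4.43 CPM, against 866.8 ± 11.7 to 7606 ± 370 CPM for the 41 interferon-stimulated genes. The fibroblast and endothelial markers PECAM1 and PDGFRB, the 2 measured of that list, rose by 1.63 and 1.23.

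Lysosome and autophagy genes rose in 19 of 32 and fell in 7 with tetracycline (median 0.47, adjusted p = 0.00211), with the protease CTSZ at 1.77. p53 targets rose in 16 of 23 and fell in 3 (median 0.50, adjusted p = 0.0076; adjusted p = 0.0702 with an estimated correlation), with the growth-arrest gene BTG2 going from 95.6 ± 6.68 to 632.6 ± 15 CPM. Plasma cell and B cell activation genes rose in 13 of 18 and fell in 5 (median 0.65, adjusted p = 0.0109; adjusted p = 0.0702 with an estimated correlation), the receptor FCRL5 (2.92) upward and the plasma cell marker SDC1 downward (−2.15). Camera called 23 of 29 lists with tetracycline, and 14 of these held with an estimated correlation. Counts adjusted over the list alone were the same as over all genes, except that 61 cytosolic ribosomal protein genes, 1 heat shock gene and 5 aryl hydrocarbon receptor targets rose.

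**Figure D2:**
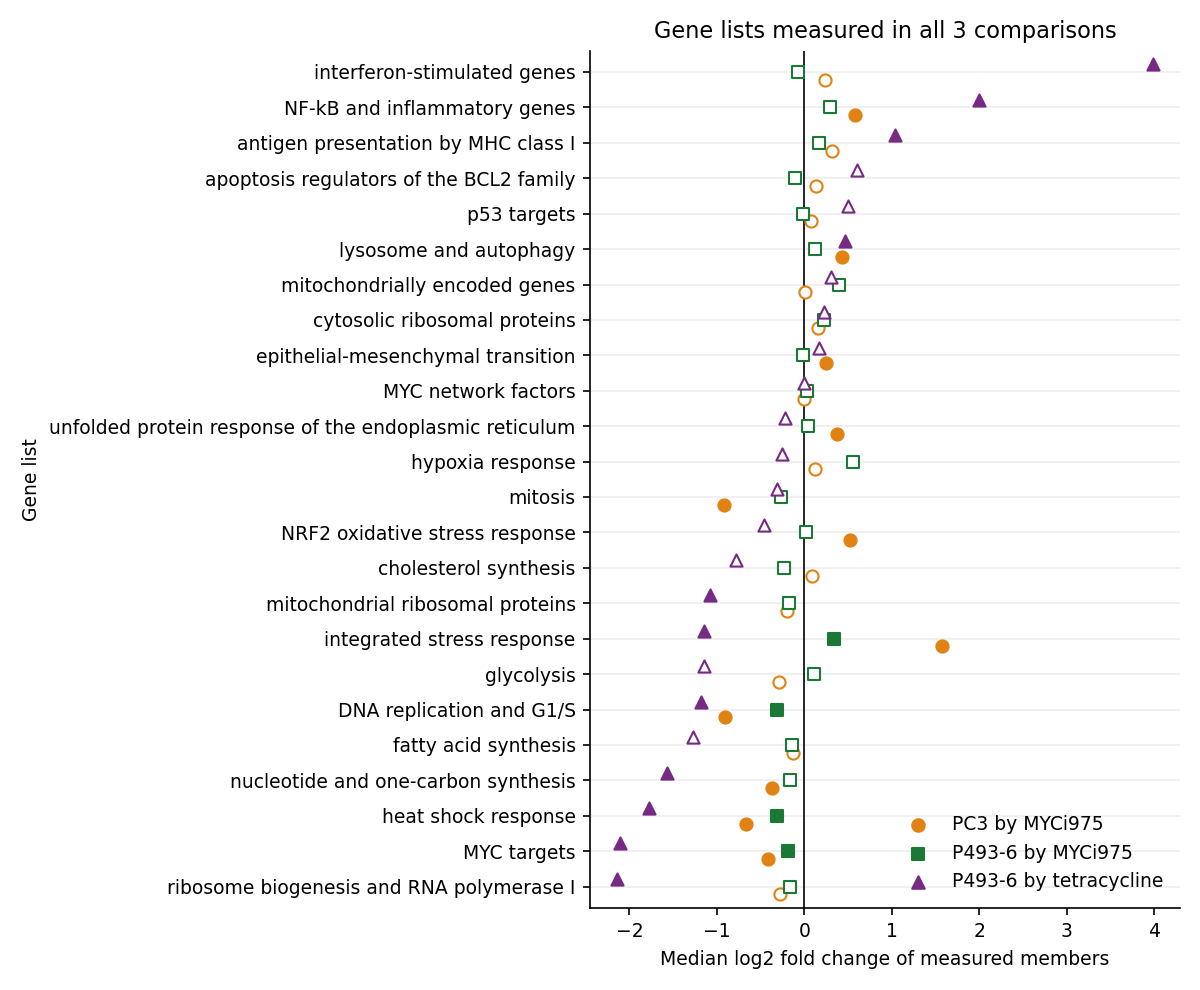
Median log2 fold change of the 24 gene lists tested in all 3 comparisons with control; circles are PC3 with MYCi975, squares P493-6 with MYCi975 and triangles P493-6 with tetracycline, and filled symbols had an adjusted p below 0.05 with both the preset and the estimated correlation. Integrated stress response genes lie at 1.57 and 0.34 with MYCi975 and at −1.15 with tetracycline, interferon-stimulated genes at 3.99 with tetracycline, and MYC targets below 0 in all 3 (−0.41, −0.19 and −2.11).

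The direct contrast of MYCi975 with tetracycline in P493-6 asked where the compound and the shutdown of MYC differ. MYC targets, ribosome biogenesis and stress response genes were higher with MYCi975 than with tetracycline, and interferon-stimulated, B cell and inflammatory genes were lower. MYC was 5118 ± 29.4 CPM with MYCi975 against 149.0 ± 3.75 CPM with tetracycline (log2 difference 5.09, SE 0.034, adjusted p = 2.65e-61). Next came ASS1 (175.8 ± 4.73 against 5.90 ± 0.579 CPM, 4.68), CAMKV (4.68), DDN (4.45) and PODXL2 (4.28). The lowest with MYCi975 were IFI6 (1.09 ± 0.259 against 175.5 ± 15.5 CPM, −6.40), IFI44L (−6.21), MX1 (−6.15) and SLFN5 (−5.83). Of 12860 genes, 9794 differed, 5438 higher and 4356 lower with MYCi975, 1954 and 1426 of them by at least 2-fold, and the groups did not overlap for 76.9% of genes against 10% by chance. With TMM scaling 4884 were higher and 4929 lower, so the split by direction depended on scaling.

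Of 57 MYC targets, 53 were higher and 2 lower with MYCi975 than with tetracycline (median 1.96, adjusted p = 3.45e-20), SRM by 3.24 and RRP9 by 3.39. All 36 ribosome biogenesis genes were higher (median 2.04, adjusted p = 2.4e-18). Integrated stress response genes were higher in 22 of 26 and lower in 1 (median 1.36, adjusted p = 3.7e-07), including PSAT1 (3.56) and STC2 (3.55). Fatty acid synthesis genes were higher in 11 of 14 and lower in 2 (median 0.97, adjusted p = 0.000481), FASN by 3.35. Glycolysis genes were higher in 17 of 20 and lower in 1 (median 1.35, adjusted p = 3.7e-07; adjusted p = 0.0504 with an estimated correlation), PFKFB4 by 2.32. Interferon-stimulated genes were lower in 32 of 33 and higher in 1 (median −3.50, adjusted p = 5.24e-21), and all 24 B cell identity genes (median −1.36, adjusted p = 5.62e-14, CD72 at −3.70), all 17 NF-kB and inflammatory genes (median −1.90, adjusted p = 2.85e-10, TNF at −3.43) and all 13 MHC class II genes (median −1.67, adjusted p = 3.97e-10, HLA-DOB at −2.19) were lower. All 5 measured T cell and myeloid markers were lower too (median −2.28, adjusted p = 0.00197; adjusted p = 0.0577 with an estimated correlation). Cytosolic ribosomal protein genes did not pass (25 higher, 26 lower, median −0.002, adjusted p = 0.533), with RPL17 at 0.59 and RPS27 at −0.62, but were called lower with TMM scaling (median −0.11, adjusted p = 0.047). Camera called 23 of 28 lists, 16 of them also with an estimated correlation. Adjusted over the list alone, the counts of the lists named here were the same except for cytosolic ribosomal proteins (24 higher, 26 lower).

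**Figure D3:**
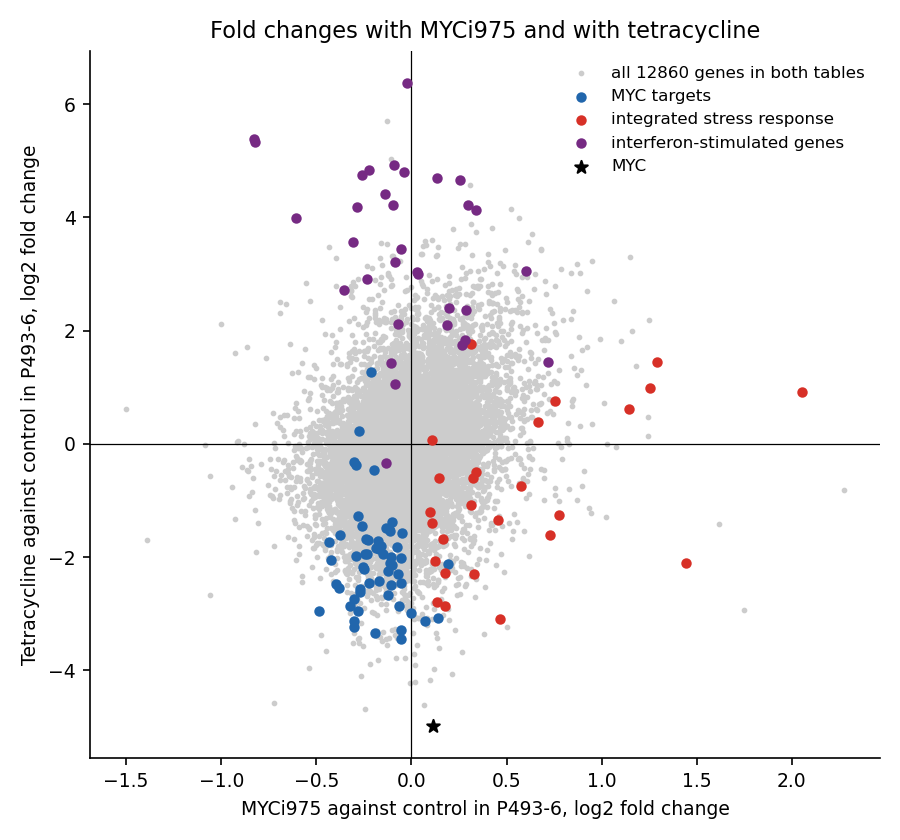
Log2 fold change against control in P493-6 with MYCi975 (x axis) and with tetracycline (y axis) for 12860 genes; each point is a gene, with MYC targets in blue, integrated stress response genes in red, interferon-stimulated genes in purple and MYC as a star. The tetracycline axis spans a wider range, and MYC lies at 0.11 on the x axis and −4.98 on the y axis.

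Across the 12860 genes tested in both P493-6 comparisons, 833 rose and 1740 fell with both treatments, against 457 and 1044 for independent lists, while 360 rose with MYCi975 and fell with tetracycline, against 610, and 334 did the reverse, against 782. With TMM scaling 1106 rose and 1244 fell with both, so the excess of shared falls over shared rises depended on scaling. Among the genes that rose with both were ATF3 and DDIT4, and among those that fell with both were PPP1R3A and HPDL. ASS1 (1.75 with MYCi975, −2.94 with tetracycline), PFKFB4 (1.02, −1.30), PDK1 (0.87, −0.99) and ATF5 (0.78, −1.25) rose with MYCi975 and fell with tetracycline, while BIK, a promoter of cell death (−0.87, 1.71), and MX1 (−0.83, 5.33) did the reverse. The fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.303. Both comparisons use the same 3 controls, and in 100 simulations of unchanged groups those alone gave a median r of 0.479 (0.455 to 0.501). The simulated groups had no treatment effect, so their r cannot be set against the observed r, and the covariances were compared instead. The covariance was 0.0748 against 0.00689 simulated, a difference of 0.0679, and at most 1 gene was called in both comparisons in any simulation. Part of the excess in the overlap may come from the shared controls, which were too few to split.

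The MYCi975 responses of PC3 and P493-6, which share no libraries, correlated with an r of 0.409 over 11240 genes. In both lines 698 genes rose and 1512 fell, against 335 and 721 for independent lists, while 207 rose in PC3 and fell in P493-6, against 631, and 131 did the reverse, against 383. With TMM scaling 894 rose and 1148 fell in both. STC2 (2.11 in PC3, 1.44 in P493-6), ATF3 (1.77, 1.29), DDIT4 (3.29, 1.25), SLC6A9 (1.17, 1.62) and ERN1 (2.33, 1.08) rose in both, and RRM2 (−1.45, −0.74), FAM111B (−2.23, −0.69), CCNE2 (−1.74, −0.67) and CLSPN (−1.13, −0.64) fell in both. ATF5 fell in PC3 (−0.66) and rose in P493-6 (0.78). PC3 with MYCi975 and P493-6 with tetracycline correlated with an r of 0.275 over 11435 genes, and 1590 genes rose and 2450 fell in both (1738 and 2308 with TMM scaling), against 1049 and 1718 for independent lists, while 1721 went opposite ways, 1041 of them up in PC3 against 1522 and 680 down in PC3 against 1184. MCM4 (−1.42, −1.73), CDC25A (−1.38, −2.12) and UNG (−1.33, −2.56) fell in both, whereas ASNS (2.73, −1.62), PHGDH (1.71, −2.30) and PSAT1 (1.46, −3.09) rose in PC3 with MYCi975 and fell in P493-6 with tetracycline.

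The difference between the 2 lines in their response to MYCi975 was tested directly as an interaction, with the dose 8 µM in PC3 and 6 µM in P493-6. Integrated stress response genes rose more in PC3, mitosis and DNA replication genes were lowered more there, and glycolysis genes had the lower change there. TRIB3 rose from 45.1 ± 1.87 to 610.4 ± 19.2 CPM in PC3 and from 39.6 ± 2.33 to 59.6 ± 4.34 CPM in P493-6 (log2 difference of the effects 3.16, SE 0.075, adjusted p = 2.67e-29). Of 11240 genes, 4075 differed in response, 2029 with the higher change in PC3 and 2046 with the higher change in P493-6 (1824 and 2353 with TMM scaling). Integrated stress response genes had the higher change in PC3 in 25 of 27 and the lower in 1 (median difference 1.01, adjusted p = 5.08e-25). The change was lower in PC3 for 28 of 30 mitosis genes (median −0.65, adjusted p = 4.9e-24), for 31 of 36 DNA replication and G1/S genes (median −0.47, adjusted p = 2.36e-17), for 30 of 57 MYC targets, with 2 higher (median −0.22, adjusted p = 2.06e-07), and for 15 of 20 glycolysis genes, with 1 higher (median −0.52, adjusted p = 3.64e-10). HSPA5 went from 536.4 ± 2.5 to 1475 ± 72.2 CPM in PC3 and from 673.4 ± 16.3 to 664.9 ± 20.2 CPM in P493-6 (1.48, SE 0.047, adjusted p = 6.7e-25). Camera called 16 of 24 lists, 11 of them also with an estimated correlation. Adjusted over the list alone, 32 MYC targets were lower and 3 higher, 29 mitosis genes were lower, and the counts of the other lists named here were the same.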

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

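The tests of scaling, single libraries, other cells, the vehicle and genes that vary together were chosen after the results were seen, although the fits with RLE scaling, without single libraries and with an estimated correlation had been planned. Results are listed because the effect of MYCi975 differed between PC3 and P493-6 in a test of the interaction, with a dose of 8 µM in PC3 and 6 µM in P493-6, so the line and the dose act together. The interaction called 4075 of 11240 genes. Of 200 possible splits of the libraries within the lines, 100 were drawn, and 3 of them, the real one included, gave as many genes, with 6245 in the highest other split, which exchanged the groups of 1 line and so measured the sum of the effects. For lists, 15 of the 100 called at least the 16 of the real split, and the highest other called 18. Most of these splits mix treated with control libraries and so remove the effects of MYCi975 along with any difference between them, so neither count tests whether the lines differ.

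Among lists, the effect was higher in PC3 for the integrated stress response (median difference 1.01), NRF2 targets (0.395), lysosome and autophagy (0.359), the unfolded protein response (0.335) and cholesterol synthesis (0.284). The BCL2 family was called too (0.048; adjusted p = 0.0822 with an estimated correlation), but its median difference was 0.104 and 0.004 without PC3 control replicates 1 and 3, 0.073 and 0.002 without PC3 MYCi975 replicates 2 and 3, 0.026, 0.077 and 0.073 without P493-6 control replicates 1, 2 and 3, and 0.014 and 0.087 without P493-6 MYCi975 replicates 1 and 2. The camera call on the BCL2 family was kept without each single library (highest adjusted p = 0.0462). Its mean difference was 0.429, with 6 of 14 genes higher in PC3 and 1 lower. The effect was lower in PC3 for mitosis (−0.645), glycolysis (−0.515), DNA replication and G1/S (−0.466), heat shock (−0.317), nucleotide and one-carbon synthesis (−0.273) and MYC targets (−0.221). It was also lower for hypoxia (−0.512; adjusted p = 0.168 with an estimated correlation), mitochondrially encoded genes (−0.336; adjusted p = 0.383), ribosome biogenesis (−0.148; adjusted p = 0.166) and cytosolic ribosomal proteins (−0.064; adjusted p = 0.593), these p-values also with an estimated correlation. The last of these was lost without PC3 control replicate 1 (−0.031, adjusted p = 0.121), PC3 MYCi975 replicate 3 (adjusted p = 0.0821), P493-6 control replicate 1 (adjusted p = 0.0852) or P493-6 MYCi975 replicate 1 (adjusted p = 0.0871).

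Among genes, the log2 difference of the effects was 0.187 for MYC, 3.156 for TRIB3, 2.24 for SESN2 and 2.037 for DDIT4. It was 2.275 for BMF, a promoter of cell death, and 2.397 for RGCC, 1.783 for HMOX1, 1.475 for HSPA5 and 1.57 for CDKN1A, all of which rose in PC3 and did not pass the test in P493-6. It was −2.288 for MAP2K6, −1.54 for FAM111B, −1.205 for PLK1, −1.058 for UNG, −0.988 for MCM4 and −1.281 for KIF20A. PDK1 rose in P493-6 and fell in PC3 (−1.225).

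Integrated stress response genes rose with MYCi975 in both lines and fell with tetracycline in P493-6. The choice among CPM, TMM and RLE scaling was argued against, because the smallest absolute median over the 3 comparisons and both other scalings was 0.383. A single library was argued against too, because the smallest absolute median without any 1 library was 0.325. All of these scalings give expression relative to the other genes, so a change in total RNA per cell was not tested. The fall with tetracycline (median −1.146) stays open as well: no group had tetracycline or its vehicle without the loss of MYC, so these cannot be told apart from the loss of MYC. A biological difference between giving the compound and removing MYC mRNA is a candidate explanation that the design does not test alone. No group separates what MYCi975 does through MYC from what it does otherwise. In P493-6 the median of the MYC targets was −0.19 with MYCi975 and −2.11 with tetracycline.

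Interferon-stimulated genes rose with tetracycline and not with MYCi975 in P493-6. The lowest median without any 1 library was 3.932, which argues against a single library. RNA from T cells or myeloid cells has no recorded source, since P493-6 is an established B cell line grown in culture. The summed rise of their markers was 2.44% of that of the interferon-stimulated genes. It went from 25.8 CPM in controls to 190.2 CPM with tetracycline, with ITGAM the most abundant at 77.8 CPM, and 8 of 16 fixed markers were measured. B cells can express some of these markers, and the libraries do not tell which cells the reads came from. The marker values alone therefore neither show nor exclude other cells. Tetracycline or its vehicle, as the source of the rise (median 3.986), cannot be told apart from the loss of MYC, since both came with it in every library.

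Cytosolic ribosomal protein genes rose while ribosome biogenesis genes fell in all 3 comparisons with control. Transcript length and GC content were tested with 10000 random sets matched on length, GC and expression. The list's median lay at the 99.76th percentile or above. The sets had medians of −0.12 in PC3, and in P493-6 −0.098 with MYCi975 and −0.286 with tetracycline, so matched genes did not rise as a set. The match was imperfect on expression (median 461 against 277 CPM in PC3, and in P493-6 963 against 455 CPM with MYCi975 and 971 against 445 CPM with tetracycline). It was also imperfect on length (1841.5 against 2139.5, 2190 and 2226 bases). Lengths were of the longest annotated transcript, which may not be the one expressed. Sets were drawn gene by gene, so their members do not vary together as the list's may. The percentiles therefore do not decide whether length or GC plays a part. The choice among CPM, TMM and RLE scaling was argued against by a lowest median of 0.159 over both other scalings. All of these give expression relative to the other genes, so a change in total RNA per cell was not tested. Ribosomal protein genes that vary together between libraries may account for part of the strength of the test. Their estimated correlation was 0.414 in PC3, and in P493-6 0.33 with MYCi975 and 0.564 with tetracycline. The call was lost in all 3 comparisons with an estimated correlation, where the lowest adjusted p was 0.057. That loss alone does not show it, since calls on lists with correlations below 0.01 were lost too. The call on ribosome biogenesis was also lost with MYCi975 in PC3 (adjusted p = 0.0904) and P493-6 (0.147), and held with tetracycline (0.0442). Reads shared with pseudogenes were not tested.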

How the results depend on the processing

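TMM scaling, edgeR quasi-likelihood on the recovered reads, 1 fit of all 9 P493-6 libraries, lists with a pseudocount of 0.1 and the overlaps under edgeR, left-out replicates and the block were added as alternatives after seeing the data. TMM scaling, edgeR and the fit of all 9 libraries had been the plan for counts. Named genes gave 243 results, each a gene in 1 comparison, so a gene named in several comparisons counts more than once. Of these, 240 kept their direction and their side of the threshold in every setting that held them. MAX in PC3, MYC in P493-6 with MYCi975 and MAX in P493-6 with MYCi975 did not keep both. All 243 were held under TMM and RLE scaling, DESeq2, limma voom, edgeR, a pseudocount of 0.1, the block and left-out replicates. A mean CPM of at least 5 held 233 results, the fit of all 9 P493-6 libraries 130, and the added tetracycline libraries 16. The fold change limit was not applied to them. The naming rule favored called genes with large changes, so these counts say little about genes with small changes. Without P493-6 control replicate 1, MAX in P493-6 with MYCi975 changed sign to −0.001, and leaving out each replicate gave −0.001 to 0.039; the cause was not tested. Leaving out each replicate gave 7458 to 7697 changed genes in PC3, 2976 to 3281 in P493-6 with MYCi975, 10273 to 10436 with tetracycline, 9404 to 9806 in the direct contrast and 3617 to 3994 for the difference between lines.

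Requiring an absolute log2 fold change of at least 1 left 507, 28, 4068, 3380 and 248 genes in these comparisons and 9, 11 and 95 shared genes in the overlaps of MYCi975 with tetracycline, of both lines, and of PC3 with tetracycline, where 2573, 2210 and 4040 had been shared, because most changes were small. DESeq2 on the recovered reads called 2447 genes in P493-6 with MYCi975, and the cause was not tested. With an estimated correlation, 11, 5 and 14 lists were called in the 3 comparisons with control. Some lost lists had high estimates, such as cytosolic ribosomal proteins in PC3 (0.414). Others had estimates below 0, such as fatty acid synthesis in P493-6 with MYCi975 (−0.032), so correlation between members cannot account for every loss. What else contributed was not tested. The r of MYCi975 and tetracycline in P493-6 was 0.336 as Spearman's rho and also 0.336 at a mean CPM of at least 5. The r of both lines was 0.47 at that CPM and 0.379 with edgeR, and the r of PC3 with tetracycline was 0.321 as rho and 0.266 with edgeR; the cause was not tested. Fry pointed the other way than camera for the MYC network factors with tetracycline (median 0) and in the direct contrast (0.021) and for mitosis in the direct contrast (−0.058), lists whose members went both ways.

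Of 135 list results, 131 were the same with TMM and 132 with RLE scaling. B cell identity in P493-6 with MYCi975 passed with TMM (adjusted p = 0.0298) and RLE (0.0309), and interferon-stimulated genes in the difference between lines (adjusted p = 0.0531) passed with TMM (0.0419), RLE (0.0482), a pseudocount of 0.1 (0.0482), fry (0.00018) and the tetracycline libraries added (0.0279), and without PC3 MYCi975 replicate 2 (0.0451) or 3 (0.0489), P493-6 control replicate 1 (0.0371) or P493-6 MYCi975 replicate 2 (0.0317); leaving out each replicate gave adjusted p from 0.0317 to 0.0855, and an estimated correlation 0.143. A replicate block was tried because replicate numbers recur, but after removing group means libraries with the same number correlated from −0.11 to 0.068 (12 pairs) and others from −0.077 to 0.09 (24 pairs), so the numbers do not pair. It gave 8220, 3274, 10655 and 9761 changed genes in PC3, with MYCi975 and with tetracycline in P493-6 and in the direct contrast, and changed the calls on MYC in P493-6 with MYCi975 (adjusted p = 0.0999) and on interferon-stimulated genes in the difference between lines (0.0471). Library size only, no filter, and only the 6 libraries are the settings already used and gave no separate values. Depth limits genes at a few CPM.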

Other observations

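The list of replication-dependent histone genes was chosen after the values were seen. In PC3 with MYCi975, 27 of 29 measured histone genes of this kind, which are transcribed in S phase, fell and none rose (median log2 fold change −0.997, camera p = 1.39e-20, p = 0.0195 with an estimated correlation). In P493-6 with MYCi975, 12 of 33 fell and none rose (median −0.09, camera p = 0.00194, p = 0.337 with an estimated correlation), and with tetracycline 11 rose, 11 fell and 11 did not pass (median 0, camera p = 0.866). The change was lower in PC3 than in P493-6 for 25 of 29 (median −0.87, p = 0.00225 with an estimated correlation). These genes come in near-identical copies, so single members are uncertain. Among factors that share partners with MYC, MXD1, a repressor that competes with MYC for MAX, rose by 1.40 in PC3 with MYCi975, 0.62 in P493-6 with MYCi975 and 1.62 with tetracycline. MXI1, a related repressor, rose by 1.02 and 0.40 with MYCi975 and was −1.88 with tetracycline, and TXNIP, an inhibitor of thioredoxin and glucose uptake, rose by 2.79 with tetracycline. The network list as a whole passed in none of them (adjusted p = 0.214, 0.224 and 1), and its median, mean and test differed in sign in PC3 (−0.002, 0.167, up) and with tetracycline (0, −0.13, up).

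BCL2 family genes, which set the threshold for cell death, rose in 7 of 15 and fell in 4 in PC3 with MYCi975 (adjusted p = 0.134), BMF by 2.13 and PMAIP1 by 1.37, and the p53 target BBC3 by 1.65. In P493-6 with MYCi975, 2 of 14 rose and 4 fell (adjusted p = 0.553), with BIK at −0.87. With tetracycline 9 of 14 rose and 3 fell (median 0.61, adjusted p = 0.00829; adjusted p = 0.0702 with an estimated correlation), with the survival genes BCL2A1 at 2.95 and BCL2 at 1.97. Of 17 epithelial and prostate identity genes in PC3, 5 rose and 6 fell (adjusted p = 0.581), with the prostate transcription factor HOXB13 at −0.97. Cholesterol synthesis genes in PC3 rose in 12 of 25 and fell in 6 (adjusted p = 0.134), and fatty acid synthesis genes rose in 4 of 14 and fell in 7 (median −0.13, mean 0.03, test down, adjusted p = 0.661). The autophagy gene WIPI1 rose by 1.58 in PC3. Targets of the aryl hydrocarbon receptor, a sensor of foreign compounds, passed neither in PC3 (2 of 5 rose, 1 fell, adjusted p = 0.682) nor with tetracycline (4 of 5 rose, adjusted p = 0.0597). ENSG00000277048, without a gene name, lies on a sequence assigned to chromosome 22 without a position. It held the most reads of any listed gene in 13 of the 15 libraries (RN7SK in the other 2). Its share ranged from 1.23% in PC3 MYCi975 replicate 2 to 5.03% in P493-6 tetracycline replicate 3. With tetracycline it was 4.14%, 4.04% and 5.03%, against 2.07%, 2.79% and 3.66% in P493-6 controls. What this sequence encodes was not tested.

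With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In PC3 the real split called 8137 genes, 19 lists and an absolute MYC target median of 0.413, and the highest other split called 0 genes by limma (146 at an unadjusted p below 0.05), 15 lists and a median of 0.158. In P493-6 with MYCi975 the real values were 3713 genes, 19 lists and 0.191, and the highest others 0 (476 unadjusted), 14 and 0.085. With tetracycline they were 10702, 23 and 2.109 against 0 (53 unadjusted), 22 and 0.727, and in the direct contrast 9794 genes and 23 lists against 0 (139 unadjusted) and 22. The other splits still part the groups 2 to 1, so a share of the effect remains in their list tests.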
